A study of Oryza sativa with 30 samples.

How the data were processed

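Shoot apices of 2 rice cultivars were sampled on 4 days, and the deposited files hold 1 column of whole-number counts per gene for each of 23 libraries. Plants were grown at 28 °C by day and 24 °C by night, apices were dissected under a microscope, total RNA was extracted with a column kit and libraries were made and sequenced by a company, per the labels' protocols. Per the submitters' processing notes the authors' tools included Bowtie2, TopHat2, HTSeq, R 3.1.0 and edgeR 3.6.4, and the deposited counts are raw counts per gene with no normalization. The roles of these tools beyond their names, the genome build, the annotation release and whether counting used strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The files name genes by MSU locus identifiers and give neither symbols nor coordinates. Counts of 55986 loci were used, of which 185 on unplaced sequences had 0 counts in every library. The 5 summary lines of each file were left out of library sizes and tests: reads in no gene came to 4.72 to 5.51% and ambiguous reads to 2.01 to 2.44% of assigned reads. Reads aligned to several places are not among the gene counts, so near-identical genes can be undercounted, and values for PIN1c and PIN1d, OsRR9 and OsRR10, HSP16.9A and HSP16.9B, the RBCS genes and the LHCB and CAB genes are uncertain for that reason.

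Groups were taken from the labels' cultivar and day. The time of day of collection is not given in the sources used here. The labels number the replicates but do not say that they came from separate plants or harvests, so p-values measure the spread between these libraries, which may be technical in part. Libraries of a group were not duplicates, since the chi-square per gene between them was 5.93 to 51.5. Replicate numbers were not shown to pair libraries across days, since 9 of 33 same-numbered pairs had deviations correlated above 0.1, so no block was used. Differently numbered pairs were not compared, so pairing is not excluded. Among NB day 4, 8 and 12 the correlations of same-numbered pairs were all positive (0.061 to 0.496).

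Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 on the deposited counts, with TMM scaling and filterByExpr on the groups, which left 22839 genes. All 8 groups entered 1 model with 15 residual degrees of freedom, and the common biological coefficient of variation was 12.7%. There were 10 comparisons: each later day against day 0 within a cultivar, the interaction between cultivar and each later day, and T65 against NB with the 4 days weighted equally. P-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. CPM (counts per 1e+06) use TMM-scaled library sizes, and the SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Where a group has few counts, this SE can be smaller than counting error. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 17 lists and 6 comparisons (102 tests). Of these 26 passed, and with an estimated correlation 2 held, those of the inflorescence identity genes at NB day 8 and day 12. Fry, planned beside camera, asks whether a list moved at all, not whether it moved more than other genes. At an adjusted p under 0.05 it lost panicle genes at T65 day 4 and 12 and leaf genes at T65 day 4. It also lost YABBY genes at NB day 8 and T65 day 8 and inflorescence genes at T65 day 8. Cellulose synthases at NB day 8 and cell division at NB day 12 were lost as well, and the rest of the 26 held. Fry also called lists that camera did not.

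The comparisons, the tests, 18 gene lists of 186 genes, the rule for named genes and most of the alternative settings were chosen before the data were examined. The lists were inflorescence identity MADS-box genes, floral organ identity, SVP-like and SOC1-like MADS-box genes, photoperiodic flowering, panicle branching and spikelet meristem, the SPL family, KNOX and BELL homeobox genes, YABBY genes, gibberellin, cytokinin, auxin, the circadian clock, cell division, primary wall cellulose synthases, secondary wall and vascular genes, green leaf photosynthesis, heat shock and wounding as signs of sample handling, and PINE1 by itself. OsMADS51 was placed in the SVP and SOC1 list without a check that it belongs to either family, so counts of that list are not counts of the families. PINE1 and the inflorescence MADS-box genes are known from work on the floral transition in rice that may have drawn on these same libraries, so their direction is not independent evidence. The shoot apex also holds young leaves and vascular strands, so genes of the other-tissue lists are expressed in the sampled tissue. Symbols were paired with loci from nomenclature as recalled, with no MSU annotation at hand, and checked against the symbols and chromosomes of a RefSeq gene table of assembly ASM3414082v1. That table has no MSU identifiers: 136 symbols were found on the chromosome of the locus, 46 were not in the table (PINE1, FTL1, APO1, OsFD1, RCN2, Ehd1 and GA2ox6 among them, whose pairs are thus unchecked) and 4 lay on another chromosome and were dropped, leaving 182 genes. For 132 of these, 870 of 871 pairs on a chromosome stood in the same order, which tests the pairs only in part.

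Named genes were PINE1, OsMADS14, OsMADS15, OsMADS18 and OsMADS34, up to 4 members of each list with the smallest adjusted p under 0.05 (or the smallest p where none passed), list members that passed in the interactions and the cultivar contrast, and genes of the largest fold change with a mean of at least 1 CPM and no overlap between groups, of which at most 2 per direction are named. The counts of lists are given over all genes tested and, where stated, also adjusted over the list alone. A fold against 0 counts is a lower bound from a floor of 3 counts over the group, a group with 1 to 3 counts is given as a ratio with its exact 95% counting interval, and such intervals cover counting error only.

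The steps were tested on simulated data with a random set of genes, of a mean of at least 1 CPM, changed by known folds. Counts were drawn from the real means of each cultivar over all days, the real dispersions and the real library sizes. For NB day 4 the share recovered was 52.2% at 1.5-fold, 76.1% at 2-fold and 97% at 4-fold among 22506 genes, and for T65 day 12 it was 32.8%, 67.2% and 89.4% among 22504 genes. Of the calls in these simulated data, 3.85% for NB day 4, 8.07% for NB day 12 and 5.97% for T65 day 12 were unchanged genes. The simulation gave each gene the same spread in all groups and no difference between libraries in multiply aligned reads. Its shares therefore do not measure false calls from unequal spread, such as the wider spread among the real NB day 4 libraries. In a simulation of NB day 12 camera found the raised list and called 0 of 19 unchanged lists. Its genes were drawn independently, so it does not test false calls that come from correlation between members of a list.

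Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, only the compared groups in the model, a replicate block, and each library left out in turn. A term for the split of libraries by multiply aligned reads, and the 16 or the 7 libraries of either side of it alone, were added after the data were seen. The split was set at 8% of assigned reads.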

Results

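Gene expression was measured by RNA sequencing in shoot apices of rice (Oryza sativa) as plants moved from vegetative growth towards flowering. The apex holds the shoot apical meristem, which produces leaves before the floral transition and the panicle after it. Apices of 6-week-old plants of the temperate japonica cultivars Nipponbare (NB) and Taichung 65 (T65) were collected in long days (16 h light and 8 h dark), called day 0, and after 4, 8 and 12 short days (10 h light and 14 h dark). The 30 samples in the labels correspond to 23 count libraries, because sets of sequencing runs of the same material had been merged into 5 of the libraries. Each of the 8 groups of cultivar and day held 3 libraries, except T65 day 12 with 2. Total counts in genes ranged from 8.61 M (T65 day 12 replicate 2) to 24.9 M (NB day 4 replicate 2), where M is 1e+06. The values below are CPM (counts scaled to library totals of 1 M) as mean ± SD over the libraries of a group, and log2 fold changes with their standard error (SE). For genes with few counts in a group the SE can understate the error. Genes are given by symbol and by their MSU locus identifier, since the files hold no coordinates and the genome build is not given in the sources used here.

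Libraries differed most between the cultivars, which the first principal component of log2 CPM separated (44.4% of the variance), while the second held 11.1% and the third 8.24%. On the second component NB day 4 replicate 1 (-55.84) and T65 day 12 replicate 2 (-48.68) lay at the low end, with 12.4 M and 8.61 M counts. Both had been merged from several runs, but so had NB day 8 replicate 1 (11.9 M counts), which lay at 3.56. The share of reads aligned to several places, relative to reads assigned to genes, split the libraries into 7 with 5.76 to 6.71% and 16 with 9.59 to 10.9%. The lower set held replicate 3 of NB day 8 and of NB day 12, replicates 2 and 3 of T65 day 0, replicate 1 of T65 day 4 and replicates 1 and 2 of T65 day 8. The second component followed this split within T65, whose lower set lay at 14.85 to 25.18 and whose other libraries lay at -48.68 to -4.73. Replicate 3 of NB day 8 (31.35) and of NB day 12 (54.02) also lay above the other libraries of their groups. LOC_Os01g51740 had 0 counts in all 7 libraries of the lower set and 105 to 338 counts in each of the 16 others. With the cultivar and day groups in the model, 959 genes differed across this split, so counts of changed genes from the 16 libraries of the higher share alone are given for each comparison.

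The first question was how the apex of NB responded to short days. After 4 short days the inflorescence identity genes OsMADS14 (LOC_Os03g54160) and OsMADS18 (LOC_Os07g41370), MADS-box genes related to APETALA1 and FRUITFULL, were already higher in NB, whereas genes of DNA replication and the cell cycle were lower. OsMADS18 rose from 29.7 ± 5.93 to 84.5 ± 24.6 CPM (log2 fold change 1.5 ± 0.18) and OsMADS14 from 0.484 ± 0.0631 to 2.01 ± 0.425 CPM (2.00 ± 0.43). PINE1 (LOC_Os12g42250), a zinc-finger transcription factor that restrains internode elongation, stood at 137 ± 26 CPM on day 0 and 99.8 ± 24.7 CPM on day 4, a difference that did not pass the edgeR quasi-likelihood test (-0.46 ± 0.23, Benjamini-Hochberg adjusted p = 0.179). OsMADS15 (LOC_Os07g01820, 7 counts on day 0 and 11 on day 4) and OsMADS34 (LOC_Os03g54170, 6 and 1 counts) were near the limit of detection.

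Of the 14 cell division genes, 12 fell at NB day 4 (13 adjusted over the list alone), with a median log2 change of -0.56. Among them were MCM4 (LOC_Os01g36390, -0.85 ± 0.13), MCM5 (LOC_Os02g55410, -0.79 ± 0.13) and MCM6 (LOC_Os05g14590, -0.76 ± 0.12), subunits of the replicative helicase, and the mitotic cyclin CYCB2-1 (LOC_Os04g47580, -0.58 ± 0.08). The list was lower than other genes by camera with a preset correlation (adjusted p = 1.77e-08), a call that was lost with an adjusted p = 0.299 with an estimated correlation. Of 10 circadian clock genes, 6 rose (6 adjusted over the list alone), led by the pseudo-response regulators PRR95 (LOC_Os09g36220, 1.60 ± 0.18) and PRR37 (LOC_Os07g49460, 0.96 ± 0.12) and by GI (LOC_Os01g08700, 0.77 ± 0.12), which acts in the photoperiod pathway. Camera gave the clock list an adjusted p = 6.77e-05, and an adjusted p = 0.151 with an estimated correlation. The time of day of collection is not given in the sources used here, so changes of clock genes, here and below, are not told apart from a shift of sampling time relative to the light period.

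Among 18 SPL genes, which encode SBP-box transcription factors, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with OsSPL14 (LOC_Os08g39890) at 0.92 ± 0.19 and OsSPL13 (LOC_Os07g32170) at 0.74 ± 0.17. Of 11 panicle branching genes, 2 rose (3 adjusted over the list alone): PLA1 (LOC_Os10g26340, 1.02 ± 0.24), a cytochrome P450 that affects the rate of leaf initiation, and RFL (LOC_Os04g51000, 1.07 ± 0.26), the rice relative of LEAFY. In the photoperiodic flowering list, OsFD1 (LOC_Os09g36910), a bZIP partner of florigen, rose by 0.96 ± 0.19 and GF14c (LOC_Os08g33370), a 14-3-3 protein gene, fell by 0.47 ± 0.09. These were 2 of its 9 tested members (1 and 1 adjusted over the list alone). The floral organ genes OsMADS2 (LOC_Os01g66030, 0.55 ± 0.12) and OsMADS16 (LOC_Os06g49840, 0.71 ± 0.24) rose, as 2 of 4 tested (2 adjusted over the list alone). Of 6 primary wall cellulose synthase genes, 3 fell (3 adjusted over the list alone), such as CESA8 (LOC_Os07g10770, -0.42 ± 0.08). In the gibberellin list, GID2 (LOC_Os02g36974), an F-box gene of gibberellin signalling, fell by 0.55 ± 0.08, and the receptor gene GID1 (LOC_Os05g33730) and KS1 (LOC_Os04g52230) of gibberellin synthesis rose, as 2 higher and 1 lower of 15 (2 and 1 adjusted over the list alone).

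Smaller numbers passed in the other lists at NB day 4. OSH71 (LOC_Os05g03884) fell as 1 of 7 homeobox genes of the KNOX and BELL classes (1 adjusted over the list alone). The cytokinin oxidase gene CKX9 (LOC_Os05g31040) rose and the response regulator gene OsRR9 (LOC_Os11g04720) fell among 11 cytokinin genes (1 and 1 adjusted over the list alone). PIN1a (LOC_Os06g12610), an auxin efflux carrier gene, rose among 6 auxin genes (0 adjusted over the list alone). No gene passed in the YABBY list or, here and in every other comparison, in the list of secondary wall and vascular genes (0 and 0 adjusted over the list alone). No gene of the SVP and SOC1 list passed either (1 higher and 1 lower adjusted over the list alone). Of 10 green leaf photosynthesis genes, LHCB-b (LOC_Os03g39610, 1.28 ± 0.36) and CAB2R (LOC_Os01g41710, 1.80 ± 0.53) rose (2 adjusted over the list alone). Of 10 genes chosen as signs of sample handling, the heat shock chaperone gene HSP101 (LOC_Os05g44340) rose from 10.7 ± 2.23 to 42.9 ± 21.8 CPM. The jasmonate-responsive JAZ8 (LOC_Os09g26780) fell (-1.68 ± 0.34, 1 and 1 adjusted over the list alone), beside the changes in cell division and clock genes.

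In all, 2292 genes were higher and 2339 lower at NB day 4 than at day 0 out of 22839 tested (4631, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The extremes included LOC_Os02g45450 (146 against 3 counts, a ratio of 55.7 with a 95% counting interval of 18.7 to 273) and LOC_Os09g35020 (5.24 ± 1.06) upwards, and LOC_Os02g03710 (-3.48 ± 0.61) and LOC_Os02g20360 (-3.23 ± 0.59) downwards. The total was 1106 when only the 2 groups entered the model (NB day 12 then gave 4214), 3071 in the 16 libraries of the higher share, 2328 without day 4 replicate 1, 2641 without day 0 replicate 2, and 6982 without day 4 replicate 2. Of 34 named list genes that passed (at most 4 per list), 14 lost their call without at least 1 library, including RFL, GID1, KS1, OsMADS16, OSH71, CKX9, OsRR9, PIN1a, LHCB-b and CAB2R.

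After 8 short days NB apices showed large increases of inflorescence identity genes and a loss of PINE1 transcript. OsMADS14 reached 22.9 ± 6.85 CPM (log2 fold change 5.56 ± 0.34), OsMADS15 11.8 ± 7.22 CPM against 0.104 ± 0.0534 on day 0 (6.80 ± 0.60) and OsMADS18 a mean of 153 CPM (2.36 ± 0.18). PINE1 fell from 137 ± 26 to 27.7 ± 11.1 CPM (-2.32 ± 0.25, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.23e-05). FTL1 (LOC_Os01g11940), a member of the florigen family, rose from 0.13 ± 0.0695 to 2.25 ± 0.78 CPM (4.06 ± 0.39). Hd3a (LOC_Os06g06320), a florigen gene transcribed in leaves, and Ehd1 (LOC_Os10g32600), its activator, had 0 counts in all 23 libraries, which allows up to 0.12 to 0.348 CPM depending on the library.

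Of the 4 tested inflorescence identity genes 3 rose at NB day 8 (4 adjusted over the list alone), and camera gave an adjusted p = 3.03e-12, and 0.00352 as adjusted p with an estimated correlation. OsMADS34, a SEPALLATA-like gene, had 16 counts against 6 and did not pass (1.90 ± 0.85). FTL1 and GF14b (LOC_Os04g38870, a 14-3-3 protein gene, 0.37 ± 0.08) rose as 2 of 9 photoperiodic flowering genes (2 adjusted over the list alone). The photoperiod list had a camera adjusted p = 0.00793 and an adjusted p = 0.274 with an estimated correlation. Of 10 clock genes, PRR73 (LOC_Os03g17570, 0.64 ± 0.08), PRR95 (1.19 ± 0.18), GI (0.71 ± 0.12) and PRR37 (0.59 ± 0.12) rose (4 adjusted over the list alone). The clock list had a camera adjusted p = 0.0361 and an adjusted p = 0.467 with an estimated correlation. Of 10 leaf photosynthesis genes, 3 rose (6 adjusted over the list alone), among them CAB1R (LOC_Os09g17740), a gene for a chlorophyll-binding protein, to 49 ± 5.74 CPM (2.00 ± 0.28). The leaf list had a camera adjusted p = 6.76e-05 and an adjusted p = 0.328 with an estimated correlation. No cell division gene passed (0 adjusted over the list alone, median 0.05).

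Single members passed in other lists at NB day 8: OsSPL13 (0.83 ± 0.17), OsYAB5 (LOC_Os04g45330, 0.52 ± 0.14) and GA2ox6 (LOC_Os04g44150, a gibberellin-inactivating enzyme, 0.89 ± 0.22) rose, and OSH71 (-0.52 ± 0.13) and JAZ8 (-1.35 ± 0.34) fell. Adjusted over the list alone, 4 YABBY genes rose, 2 homeobox genes fell, and 2 gibberellin genes rose and 1 fell. In the SPL and in the handling list 1 rose and 1 fell. Camera called the YABBY list higher (adjusted p = 0.0377) and the primary wall cellulose synthases lower (adjusted p = 0.0372), both with an adjusted p = 0.467 with an estimated correlation. In all 289 genes were higher and 216 lower (505, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with LOC_Os04g29310 (5.67 ± 0.56) among the largest increases and LOC_Os05g10370 (-5.12 ± 0.73) and LOC_Os09g30190 (-4.26 ± 0.88) the largest decreases that met the naming rule. The count was 904 by DESeq2, 1703 with no filter, 97 in the 16 libraries of the higher share, and 178, 242, 290 and 167 without day 0 replicate 1, day 0 replicate 3, day 8 replicate 1 and day 8 replicate 3. Of 18 named list genes that passed, 9 lost the call without at least 1 library: GF14b, OsSPL13, OSH71, OsYAB5, GA2ox6, PRR37, CAB2R, LHCB-d and JAZ8.

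After 12 short days all 4 tested inflorescence identity genes were higher in NB (4 adjusted over the list alone). OsMADS15 reached 190 ± 54.3 CPM (log2 fold change 10.76 ± 0.53), OsMADS14 97.1 ± 33.5 CPM (7.63 ± 0.34), OsMADS18 219 ± 15.3 CPM (2.88 ± 0.18) and OsMADS34 a mean of 29.5 CPM from 6 counts on day 0 (8.28 ± 0.54). PINE1 fell to 5.81 ± 2.36 CPM (-4.55 ± 0.29, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.2e-10), and FTL1 rose to 17 ± 1.24 CPM (6.95 ± 0.36). OsMADS50 (LOC_Os03g03070), a SOC1-like floral activator, fell from 75.4 ± 1.68 to 34.2 ± 0.891 CPM (-1.14 ± 0.11).

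Of 11 panicle branching genes, 6 rose and 2 fell at NB day 12 (7 and 2 adjusted over the list alone). NL1 (LOC_Os05g50270, 2.43 ± 0.27), a GATA factor that limits bract growth, LOG (LOC_Os01g40630, 1.31 ± 0.17), which activates cytokinin in the meristem, SNB (LOC_Os07g13170, 0.74 ± 0.11), an AP2-like factor of spikelet meristems, and RFL (1.28 ± 0.26) were among those that rose. The panicle list had a camera adjusted p = 0.00751 and an adjusted p = 0.431 with an estimated correlation. The inflorescence identity list had a camera adjusted p = 7.27e-14, and 0.00332 as adjusted p with an estimated correlation. Of the 6 genes in the SVP and SOC1 list, 2 rose and 3 fell (2 and 3 adjusted over the list alone). OsMADS51 (LOC_Os01g69850, -0.46 ± 0.09) and OsMADS47 (LOC_Os03g08754, -0.63 ± 0.13) were lower and OsMADS56 (LOC_Os10g39130, 0.91 ± 0.23) was higher. Of 9 photoperiodic flowering genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), RCN2 (LOC_Os02g32950), a relative of TERMINAL FLOWER 1, among the former (2.12 ± 0.42). For this list camera gave an adjusted p = 0.0138 and an adjusted p = 0.299 with an estimated correlation. Of 18 SPL genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with OsSPL13 at 599 ± 70.2 CPM (1.34 ± 0.18). In the floral organ list 1 of 4 tested genes fell, DL (LOC_Os03g11600, -0.89 ± 0.22, 1 adjusted over the list alone).

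Gibberellin genes moved in both directions at NB day 12, with 4 of 15 higher and 3 lower (4 and 4 adjusted over the list alone). GA2ox6 (1.76 ± 0.22) inactivates gibberellin, whereas KS1 (0.65 ± 0.11), KAO (LOC_Os06g02019, 1.27 ± 0.24) and GA20ox1 (LOC_Os03g63970, 0.62 ± 0.17) belong to its synthesis, and all of these rose. Of 7 YABBY genes, which act in lateral organs, 3 rose and 1 fell (3 and 1 adjusted over the list alone), with OsYAB5 at 0.90 ± 0.14 and OsYAB3 (LOC_Os10g36420) at 0.82 ± 0.11. For the YABBY list camera gave an adjusted p = 0.0377 and an adjusted p = 0.467 with an estimated correlation. The auxin efflux carrier genes PIN1c (LOC_Os11g04190, 0.87 ± 0.15) and PIN1d (LOC_Os12g04000, 0.97 ± 0.19), near-identical copies whose reads can be shared, rose as 2 of 6 (3 adjusted over the list alone). Of 11 cytokinin genes 3 fell (4 adjusted over the list alone), such as CKX2 (LOC_Os01g10110, -2.10 ± 0.51). Of 6 primary wall cellulose synthases 4 fell (5 adjusted over the list alone), CESA3 (LOC_Os07g24190) by -0.47 ± 0.09. For the cellulose synthases camera gave an adjusted p = 0.00343 and an adjusted p = 0.431 with an estimated correlation. CYCB1-1 (LOC_Os01g59120, 0.31 ± 0.08) and PCNA (LOC_Os02g56130, the replication clamp, 0.53 ± 0.15) rose as 2 of 14 cell division genes (2 adjusted over the list alone). The camera result for cell division was an adjusted p = 0.041 and an adjusted p = 0.759 with an estimated correlation. Of 10 clock genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), GI by 0.69 ± 0.12. Of 10 leaf photosynthesis genes 5 rose (7 higher and 1 lower adjusted over the list alone), CAB1R to 56.4 ± 24.4 CPM. The camera result for leaf genes was an adjusted p = 0.00976 and an adjusted p = 0.467 with an estimated correlation. JAZ8 fell to 8.67 ± 2.9 CPM.

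In all 1456 genes were higher and 1567 lower at NB day 12 (3023, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). LOC_Os10g18870 had 0 counts on day 0 and 226 on day 12, at least 104-fold higher against a floor of 3 counts over the group, and LOC_Os01g12110 (-5.79 ± 0.56) and LOC_Os09g37967 (-5.17 ± 0.86) fell most. The count was 4214 with only the 2 groups in the model, 1187 in the 16 libraries of the higher share, and 1345, 1781, 1590 and 1837 without day 0 replicate 1, day 0 replicate 3, day 12 replicate 1 and day 12 replicate 3. Of 49 named list genes that passed (at most 4 per list), 31 passed whichever library was left out. Those that did not included DL, OsMADS56, GA20ox1, CKX2, CYCB1-1 and PCNA.

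**Figure D1:**
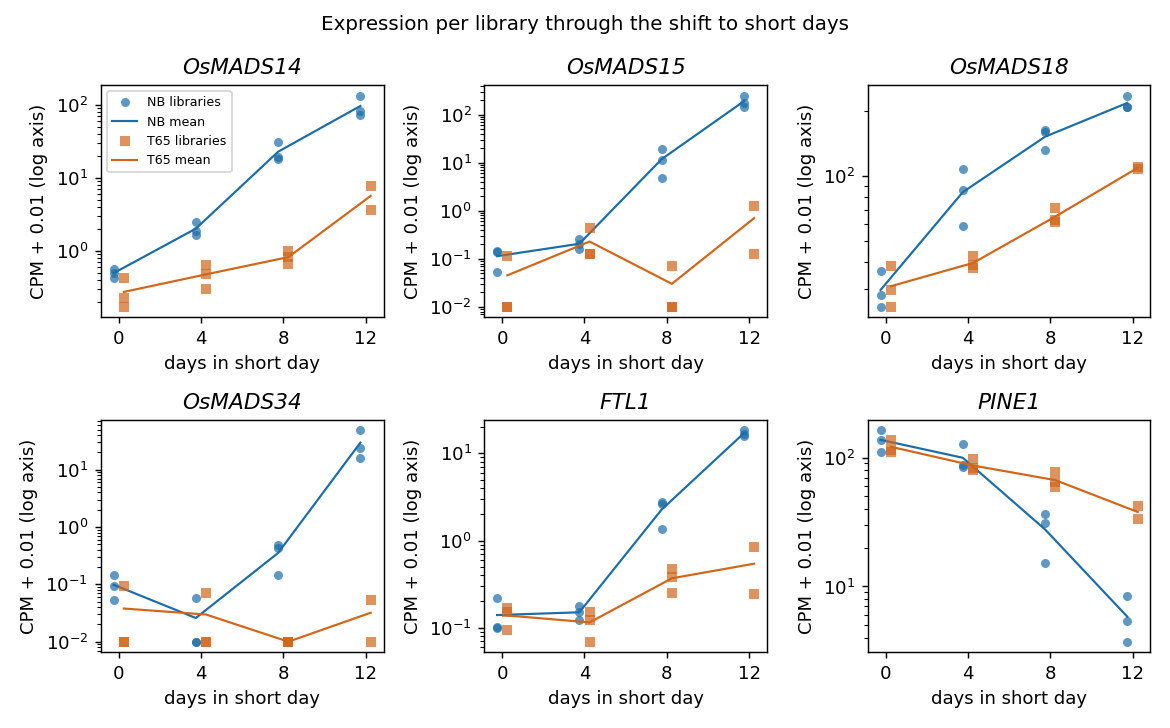
CPM per library, with 0.01 added on a log axis, against days in short day for each cultivar, with lines joining group means. OsMADS14 reached a mean of 97.1 CPM in NB and 5.66 CPM in T65 on day 12, and PINE1 reached 5.81 and 37.9 CPM.

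The same shift was then examined in T65. After 4 short days clock genes formed the group of list genes that changed in T65. PRR95 rose to 165 ± 22.9 CPM (log2 fold change 1.14 ± 0.18), GI from 220 ± 8.35 to 372 ± 11.3 CPM (0.76 ± 0.12) and PRR73 from 222 ± 12.8 to 311 ± 15.1 CPM (0.49 ± 0.08), as 3 of 10 clock genes (4 higher and 1 lower adjusted over the list alone). OsMADS18 stood at 39.6 ± 2.83 against 30.9 ± 6.78 CPM (0.36 ± 0.18), OsMADS14 at 0.466 ± 0.176 against 0.263 ± 0.136 CPM (0.69 ± 0.68) and PINE1 at 86.8 ± 8.97 against 121 ± 14.8 CPM (-0.48 ± 0.24), none of which passed the test. The limit on sampling time given for NB day 4 applies to these 3 clock genes.

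The clock list had a camera adjusted p = 0.0433 at T65 day 4 and an adjusted p = 0.467 with an estimated correlation. The panicle branching list (median 0.28, camera adjusted p = 0.0455) and the leaf photosynthesis list (median 0.25, camera adjusted p = 0.0361) were also called higher, with an adjusted p = 0.467 and an adjusted p = 0.55 with an estimated correlation, though no member passed singly (0 and 2 adjusted over the list alone). In all 26 genes were higher and 8 lower (34, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), while 2047 had an unadjusted p under 0.05. LOC_Os03g18130 (2.89 ± 0.53) and LOC_Os03g18870 (2.44 ± 0.22) rose most, and LOC_Os05g38860 (-1.77 ± 0.23) and LOC_Os02g46030 (-1.39 ± 0.19) fell most. Within the libraries of the higher share day 0 had 1 library, and within those of the lower share day 4 had 1, so counts there say little. The count over all libraries was 97 by DESeq2, 513 with no filter and 132 with only the 2 groups in the model. It was 17, 16 and 21 without day 0 replicates 1, 2 and 3 and 21, 14 and 17 without day 4 replicates 1, 2 and 3. Each of the 3 clock calls was lost without at least 1 library, T65 day 0 replicate 2 in each case.

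After 8 short days OsMADS18 was higher in T65, at 65.1 ± 5.24 CPM (log2 fold change 1.07 ± 0.18, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00349). OsMADS14 (0.81 ± 0.158 CPM, 1.52 ± 0.60), FTL1 (18 against 7 counts, 1.48 ± 0.54) and PINE1 (66.9 ± 9.26 CPM, -0.86 ± 0.24) did not pass. The clock genes GI (1.12 ± 0.12), PRR95 (1.35 ± 0.18) and PRR73 (0.63 ± 0.08) rose as 3 of 10 (6 higher and 2 lower adjusted over the list alone). The meristem homeobox genes OSH3 (LOC_Os03g51710, -0.94 ± 0.20) and OSH71 (-0.56 ± 0.13) fell as 2 of 7 (6 adjusted over the list alone).

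The KNOX and BELL list had a median of -0.42 at T65 day 8 and a camera adjusted p = 1.16e-06, and an adjusted p = 0.151 with an estimated correlation. The clock list had a camera adjusted p = 0.000538 and an adjusted p = 0.229 with an estimated correlation, and the YABBY list (median 0.15) an adjusted p = 0.0433 and an adjusted p = 0.473 with an estimated correlation. The inflorescence identity list, with 1 of 4 members higher (2 adjusted over the list alone), was called higher by camera (adjusted p = 0.0372, and an adjusted p = 0.467 with an estimated correlation). Its OsMADS15 and OsMADS34 had at most 2 counts in either group, so the call rests on OsMADS14 and OsMADS18. In all 111 genes were higher and 132 lower (243, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), led by LOC_Os04g58810 (3.55 ± 0.85) and LOC_Os01g42190 (3.14 ± 0.65) upwards and by LOC_Os05g10370 (-3.20 ± 0.66) and LOC_Os09g28510 (-2.94 ± 0.47) downwards. The count was 462 by DESeq2, 844 with no filter, 2 in the libraries of the higher share (T65 day 0 and day 8 then had 1 library each) and 150 in those of the lower share. It was 69, 91 and 153 without day 0 replicates 1, 2 and 3 and 108, 145 and 76 without day 8 replicates 1, 2 and 3. OSH3 and OSH71 lost their calls without at least 1 library.

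After 12 short days T65 had gained inflorescence identity transcripts at lower levels than those listed above for NB. Of 14 cell division genes, 7 were lower than on day 0. OsMADS14 rose from 0.263 ± 0.136 to 5.66 ± 2.93 CPM (log2 fold change 4.41 ± 0.46) and OsMADS18 from 30.9 ± 6.78 to 109 ± 2.13 CPM (1.82 ± 0.19). PINE1 fell from 121 ± 14.8 to 37.9 ± 6.28 CPM (-1.66 ± 0.29, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00216), a call lost without day 12 replicate 2 (-1.52, adjusted p = 0.0883). OsMADS15 had 30 counts against 2, a ratio of 27.2 with a 95% counting interval of 6.89 to 234, and did not pass in edgeR (Benjamini-Hochberg adjusted p = 0.057) but passed in DESeq2 (adjusted p = 0.0038). OsMADS34 had at most 2 counts in every T65 group, so that no fold is given.

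Of 14 cell division genes 7 fell at T65 day 12 (11 adjusted over the list alone), with a median of -0.48, among them MCM4 (-0.64 ± 0.14), MCM6 (-0.63 ± 0.14), MCM7 (LOC_Os12g37400, -0.70 ± 0.16) and CYCB1-1 (-0.45 ± 0.09). Each of these calls was lost without day 12 replicate 2, which stood apart on the second principal component, and those of MCM4 and MCM7 also without day 0 replicate 2. The list had a camera adjusted p = 4.74e-08, and an adjusted p = 0.312 with an estimated correlation. Of 10 clock genes 5 rose (7 adjusted over the list alone), including PRR95 (1.75 ± 0.20), GI (1.02 ± 0.14) and PRR59 (LOC_Os11g05930, 0.49 ± 0.10). Clock genes had a camera adjusted p = 2.66e-05 and an adjusted p = 0.151 with an estimated correlation. The heat shock genes HSP101 (33.4 ± 6.35 to 136 ± 8.47 CPM), HSP16.9A (LOC_Os01g04370, 1.38 ± 0.399 to 7.26 ± 5.19 CPM) and HSP16.9B (LOC_Os01g04380), neighbouring copies that may share reads, rose as 3 of 10 handling genes (3 adjusted over the list alone), in the same comparison as the cell division and clock changes. The inflorescence list, with 2 of 4 higher (3 adjusted over the list alone), had a camera adjusted p = 0.000212 and an adjusted p = 0.151 with an estimated correlation.

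APO1 (LOC_Os06g45460), an F-box gene that prolongs branch formation, rose (1.88 ± 0.42) and LAX1 (LOC_Os01g61480), a bHLH gene of axillary meristems, fell (-1.63 ± 0.38) among 11 panicle branching genes (5 and 1 adjusted over the list alone). Panicle genes had a camera adjusted p = 0.0395 and an adjusted p = 0.467 with an estimated correlation. FTL1 (21 against 7 counts, 2.28 ± 0.54) and RCN2 (2.30 ± 0.58) rose as 2 of 9 photoperiodic flowering genes (4 higher and 1 lower adjusted over the list alone). OsSPL13 (0.91 ± 0.19) and OsSPL14 (0.91 ± 0.20) rose as 2 of 18 SPL genes (2 higher and 2 lower adjusted over the list alone). So did OsYAB3 and OsYAB4 (LOC_Os02g42950, 0.62 ± 0.10), as 2 of 7 YABBY genes (4 adjusted over the list alone), and GA2ox6 (1.01 ± 0.25). In the gibberellin list GID2 fell beside GA2ox6 (1 and 1 of 15, the same adjusted over the list alone). In the SVP and SOC1 list OsMADS22 (LOC_Os02g52340, 0.28 ± 0.08) rose and OsMADS51 fell by 0.59 ± 0.11 (1 higher and 2 lower adjusted over the list alone). OsRR9 fell by 1.12 ± 0.28, as 1 of 11 cytokinin genes (1 adjusted over the list alone).

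In all 663 genes were higher and 508 lower at T65 day 12 (1171, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with LOC_Os05g03130 (45 against 1 counts, a ratio of 81.5 with a counting interval of 13.9 to 3290) among the largest increases and LOC_Os01g28810 (0 counts on day 12, at least 13.4-fold lower) and LOC_Os02g40530 (-4.27 ± 0.98) among the largest decreases. Both day 12 libraries lay in the higher share of multiply aligned reads but 2 of the day 0 libraries in the lower, so day and split are partly confounded here. With the split as a term 460 genes were higher and 353 lower. The count was 97 without day 12 replicate 2 and 1881 without day 12 replicate 1, where the lone library is assumed to vary like the other groups. It was 2254 with no filter, 660 and 551 without day 0 replicates 1 and 2, and 13 in the libraries of the higher share, where day 0 had 1 library. Of 27 named list genes that passed (at most 4 per list), OsMADS14, OsMADS18, PRR95, PRR73, GI and HSP101 passed whichever library was left out, and 18 lost their call without day 12 replicate 2.

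**Figure D2:**
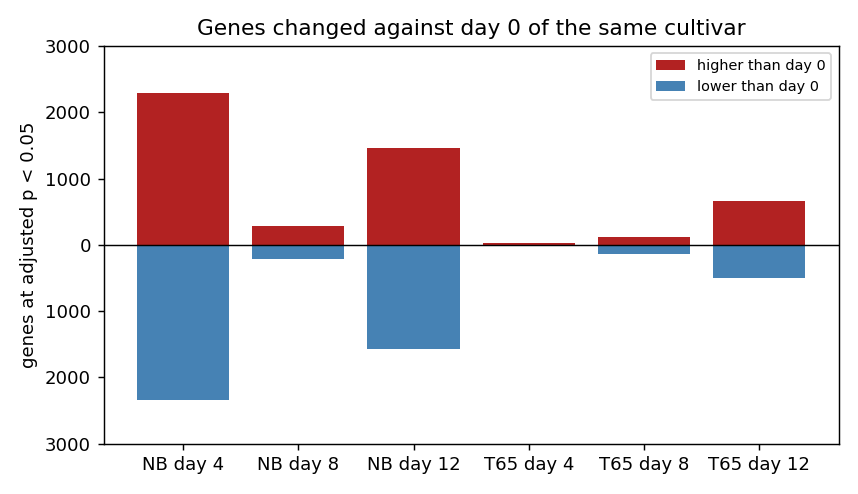
Number of genes higher (bars above 0) and lower (bars below 0) than day 0 of the same cultivar at an adjusted p under 0.05, for each day in short days. With all 8 groups in the model NB day 4 had the tallest bars (2292 higher and 2339 lower) and T65 day 4 the shortest (26 and 8), but with only the groups compared NB day 4 gave 1106 genes and NB day 12 4214.

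Genes that responded in both cultivars on day 12 were counted next, in comparisons that share no library. Of the genes tested, 169 were higher on day 12 in both cultivars, against 42.3 for independent lists of the same sizes, and 127 were lower in both, against 34.9 (one-sided Fisher's exact test, p = 1.68e-57 and p = 8.61e-39, across genes, which are not independent replicates). OsMADS14, OsMADS18, FTL1, RCN2, OsSPL13, OsSPL14, GI and PRR73 were among list genes higher in both, and PINE1 and OsMADS51 among those lower in both. A further 74 genes called in both cultivars moved in opposite directions, with APO1 and the panicle gene LAX1 (9.66 ± 2.03 CPM in NB and 1.54 ± 0.373 CPM in T65 on day 12) and the cyclin gene CYCB1-1 among them. Unlike the counts in the same direction, the 74 are not above what independent lists of the same sizes would give. The count of opposite genes was 118 and 3 without T65 day 12 replicates 1 and 2, 24 and 44 without T65 day 0 replicates 2 and 3, 21 and 25 without NB day 0 replicates 1 and 3, 36, 43 and 37 without NB day 12 replicates 1, 2 and 3, and 0 in the libraries of the higher share. It was 134 by DESeq2, 263 with no filter and 41 with the multimapping split as a term. In the libraries of the higher share T65 day 0 had 1 library, so the count there says little about opposite genes. Without T65 day 12 replicate 1 the genes lower in both were 89, against 58.6 for independent lists. The count of 296 genes changed the same way was 612 with no filter, 9 in the libraries of the higher share, 52 without T65 day 12 replicate 2, 190 without NB day 0 replicate 1 and 165 without T65 day 0 replicate 1.

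Whether the cultivars responded differently was tested by the interaction, the T65 response minus the NB response, with positive values where the change was more positive in T65. At day 4 the rise of OsMADS18 was smaller in T65 (-1.15 ± 0.25) and the cyclin genes CYCB2-1 (0.67 ± 0.12) and CYCB2-2 (LOC_Os06g51110, 0.62 ± 0.13) differed, having fallen in NB. Of 14 cell division genes 2 differed (10 adjusted over the list alone). JAZ8 (1.98 ± 0.48), GF14c (0.56 ± 0.13), GID2 (0.49 ± 0.11), KS1 (-0.63 ± 0.15) and CESA8 (0.45 ± 0.11) completed the list genes that passed. The responses of PINE1 did not differ detectably (-0.03 ± 0.33, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.99). LOC_Os02g20360 (4.53 ± 0.89) and LOC_Os01g01660 (4.36 ± 0.94) had the largest positive interactions and LOC_Os09g20390 (-3.37 ± 0.74) and LOC_Os11g44810 (-2.63 ± 0.58) the largest negative ones.

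In all 245 genes had a positive and 174 a negative interaction at day 4 (419, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 900 by DESeq2, 995 with no filter, 61 with only the 4 groups in the model and 13 in the libraries of the higher share. It was 272, 116 and 258 without NB day 0 replicates 1, 2 and 3, 178 and 1088 without NB day 4 replicates 1 and 2, 192 and 63 without T65 day 0 replicates 1 and 3, and 231 and 53 without T65 day 4 replicates 1 and 3. CYCB2-1 was the list gene that passed in each of these.

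At day 8 the interaction passed for 2 genes, both outside the fixed lists and both with a more positive response in NB. LOC_Os12g36680 rose from 2.52 ± 0.613 to 11.8 ± 2.3 CPM in NB and stood at 3.53 ± 0.205 and 5.19 ± 0.496 CPM in T65 (-1.67 ± 0.25), and LOC_Os02g50330 went from 40.7 ± 2.64 to 85.5 ± 4.08 CPM in NB and from 109 ± 8.06 to 97 ± 4.93 CPM in T65 (-1.25 ± 0.11). Estimates for OsMADS14 (-4.04 ± 0.85), OsMADS18 (-1.29 ± 0.25), FTL1 (-2.58 ± 0.77) and PINE1 (1.46 ± 0.34) did not pass in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.176, 0.129, 0.948 and 0.365). Adjusted over the list alone, 2 of 4 inflorescence identity genes and 1 of 9 photoperiodic flowering genes had a lower response in T65. No member of another list of several genes passed. PINE1, alone in its list, had a higher one only by an unadjusted p under 0.05, since a list of 1 gene gets no adjustment. The unadjusted p was under 0.05 for 948 of the 22839 genes tested. That is less than a share of 0.05, the share expected if no gene had an interaction. DESeq2 called 21. The edgeR count was 183 with no filter and 1 in the libraries of the higher share, with only the 4 groups in the model, and without NB day 0 replicate 3, NB day 8 replicate 2 or 3, T65 day 0 replicate 2 or 3, or T65 day 8 replicate 2 or 3.

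At day 12 the cultivars differed in the response of PINE1 and of inflorescence genes. The fall of PINE1 was smaller in T65 (interaction 2.89 ± 0.39, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00038), and so were the rises of OsMADS14 (-3.23 ± 0.80), OsMADS18 (-1.06 ± 0.26) and FTL1 (-4.66 ± 0.82). OsMADS15 (30 and 2 counts in T65) and OsMADS34 (1 and 2 counts) did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.302 and 0.0643), leaving 2 of 4 inflorescence genes called (3 adjusted over the list alone). OsMADS50 stood at 91.5 ± 3.03 CPM in T65 on day 12 and at 34.2 ± 0.891 CPM in NB (1.24 ± 0.16). Of 14 cell division genes 7 had a lower response in T65 (12 adjusted over the list alone, median -0.64), PCNA by -1.15 ± 0.22 and CYCB1-1 by -0.76 ± 0.12.

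Panicle branching genes split at day 12, with LAX1 (-2.54 ± 0.47), LOG (-1.06 ± 0.27) and NL1 (-1.5 ± 0.42) lower and APO1 (3.14 ± 0.59) higher in the T65 response (1 and 3 of 11, or 1 and 4 adjusted over the list alone). PIN1c (-1 ± 0.23) and PIN1d (-1.39 ± 0.28), whose reads can be shared, were lower, PRR95 (1.19 ± 0.26) and ELF3-2 (LOC_Os01g38530, 0.99 ± 0.19) of the clock were higher, and so were CESA2 (LOC_Os03g59340, 0.72 ± 0.18) and CESA3 (0.53 ± 0.14). HSP101 (1.51 ± 0.42), HSP16.9A (2.59 ± 0.73) and JAZ8 (1.88 ± 0.52) of the handling list were higher, and the leaf genes CAB1R (-1.64 ± 0.43) and LHCB-c (LOC_Os07g37240, -1.61 ± 0.48) lower. LOC_Os10g33250 rose from 2.53 ± 0.529 to 67.2 ± 34.8 CPM in NB and stood at 2.66 ± 1.14 and 1.03 ± 0.0225 CPM in T65 (-6.04 ± 0.73). In all 827 genes had a positive and 728 a negative interaction (1555, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 2432 with no filter, 237 without T65 day 12 replicate 2, 763 without T65 day 0 replicate 2, 672 and 755 without NB day 0 replicates 1 and 3, 970 and 909 without NB day 12 replicates 1 and 3, 794 with the multimapping split as a term and 13 in the libraries of the higher share. Of 31 list genes that passed, PINE1, FTL1, OsMADS50, LAX1, APO1 and CYCB1-1 did so whichever library was left out.

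**Figure D3:**
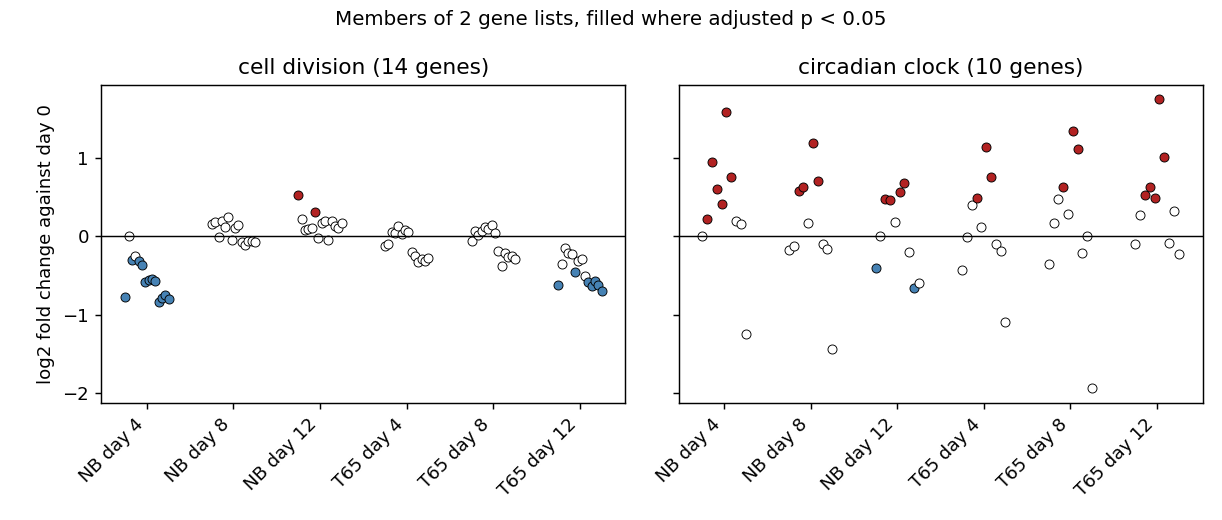
Log2 fold change against day 0 of each tested member of the cell division list (14 genes) and the circadian clock list (10 genes) in the 6 comparisons, filled where the adjusted p is under 0.05. Cell division genes had a median of -0.56 at NB day 4 and -0.48 at T65 day 12, and clock genes a median of 0.32 and 0.41.

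Averaged over the 4 days, T65 differed from NB in 29.8% of all genes tested, and no test of lists was run for this contrast. On this average all 4 inflorescence identity genes were lower in T65 (4 adjusted over the list alone), OsMADS14 by -2.92 ± 0.24. On day 0, however, the means of OsMADS18 in T65 and NB lay within the spread of either group. Hd1 (LOC_Os06g16370), the rice relative of CONSTANS, stood at 1.09 ± 0.61 CPM in T65 and 3.12 ± 1.03 CPM in NB (-1.54 ± 0.17). PINE1 was higher in T65 on this average (0.90 ± 0.13). Its mean was lower in T65 than in NB on days 0 and 4, and higher on days 8 and 12. The average over days thus includes the differences in response given above, and for PINE1 it is not a difference held on every day. Of 9 photoperiodic flowering genes 4 were lower (4 adjusted over the list alone), FTL1 by -1.96 ± 0.28. OsMADS34 lost its call without NB day 4 replicate 3, and 48 of 59 list genes that passed did so whichever library was left out.

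Of 7 YABBY genes 4 were lower in T65 (4 adjusted over the list alone), OsYAB4 by -0.55 ± 0.05. So were 3 of 11 panicle branching genes (3 adjusted over the list alone), such as the tillering regulator MOC1 (LOC_Os06g40780, -0.87 ± 0.15), and so were 6 of 10 leaf photosynthesis genes (7 adjusted over the list alone), such as RBCS3 (LOC_Os12g19381, -1.59 ± 0.21), a gene with near-identical copies. Of 10 clock genes 6 were higher and 2 lower (6 and 2 adjusted over the list alone), PRR95 at 0.68 ± 0.09 and LHY (LOC_Os08g06110) at -0.39 ± 0.06. HSP101 (1.60 ± 0.15), HSP16.9A (1.79 ± 0.26) and HSP16.9B (1.5 ± 0.40) were higher, as 3 of 10 handling genes (3 adjusted over the list alone). No cell division gene passed (0 adjusted over the list alone). LOC_Os01g38650 had 27350 counts in the T65 libraries and 4 in the NB libraries (log2 fold change 13.12), and LOC_Os10g10880 had 44783 and 11 counts (12.68). No SE is given for these genes, since at so few NB counts it falls below counting error. LOC_Os11g09850 had 2 and 24047 counts (a ratio of 10000, counting interval 2780 to 83000) and LOC_Os06g16050 1 and 11830 counts (a ratio of 9890, 1770 to 390000). For genes so low in T65, absence of the gene, reads that do not map and a difference in transcription are not told apart. In all 3395 genes were higher and 3412 lower in T65 (6807, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), of which 273 were at least 2-fold higher and 821 at least 2-fold lower. The count was 3651 in the 16 libraries of the higher share and did not move by over 1.5 times without any single library.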

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

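The counts without 1 library were planned, but setting those of NB day 4 against NB day 8, the tests on the multimapping split and the thinned counts without a T65 day 12 library were chosen only after the result was seen. The results below are listed because a test of the interaction between cultivar and day showed a difference in response between T65 and NB. At day 4 the test gave 419 genes. In the list genes the T65 response exceeded that of NB for CYCB2-1 (0.67), CYCB2-2 (0.62), GF14c (0.56), GID2 (0.485), CESA8 (0.45) and JAZ8 (1.98), and was below it for OsMADS18 (-1.15) and KS1 (-0.63). At day 8 it gave 2 genes, LOC_Os12g36680 and LOC_Os02g50330, both named after their values were seen.

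At day 12 the interaction gave 1555 genes. Flowering genes with a lower response in T65 were OsMADS14 (-3.23), OsMADS18 (-1.06), FTL1 (-4.66), LAX1 (-2.535), LOG (-1.062) and NL1 (-1.504). Those with a higher one were OsMADS16 (1.35), OsMADS50 (1.24), APO1 (3.135), OsSPL12 (0.59) and OsSPL15 (0.47). PINE1 (2.89), the internode elongation gene, also had a higher one. Of growth genes, PCNA (-1.15), CYCB1-1 (-0.76), CYCB2-2 (-0.46), MCM4 (-0.83), MCM5 (-0.705), MCM6 (-0.73) and MCM7 (-0.87) were lower in the T65 response. CESA2 (0.72), CESA3 (0.525) and the gibberellin gene GA2ox1 (2.23) were higher. The auxin carriers PIN1c (-1) and PIN1d (-1.39) and the leaf genes CAB1R (-1.64) and LHCB-c (-1.61) were lower. The clock genes PRR95 (1.185) and ELF3-2 (0.99) and the handling genes HSP101 (1.51), HSP16.9A (2.585) and JAZ8 (1.88) were higher.

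Other splits of the same libraries into groups of the same sizes were tested for the interactions at day 4 and day 8. At day 4, 3 of 40 splits gave as many genes as the real 419, with 1639 in the highest of the others. At day 8, 4 of 40 splits gave as many as the real 2, with 1414 in the highest of the others. These splits exchange cultivars within a day, which can turn the difference between cultivars (6807 genes), a structure of the samples, into an interaction. They therefore do not test chance for the interactions, and nothing is concluded from them. At day 12 T65 has 2 libraries and no such count was made.

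The first pattern weighed is that NB had more changed genes on day 4 (4631) than on day 8 (505), or 1106 and 502 with only the groups compared, although the means of OsMADS14 and OsMADS15 were higher on day 8. A single library as the whole cause is argued against by the lowest count on day 4 without 1 library, 2328, above the highest on day 8, 545. A difference in depth is argued against by counts of 3915 and 402 with every library thinned to 8.61 M. The split of libraries by multiply aligned reads does not separate NB day 0 from NB day 4, whose libraries all lie in the higher share. As the cause of a low count on day 8 the split is argued against by 4842 and 387 genes with the split as a term. The libraries of NB day 4 differed more among themselves (chi-square per gene 24.75 to 51.51) than those of NB day 0 (7.647 to 14.01) or NB day 8 (6.51 to 13.41). The checks on single libraries, depth and the split all kept a spread shared by the groups, so they do not test unequal spread. A difference in collection between the days and an early response to short days that later subsides both stay open and were not tested.

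The second pattern is that the 1171 genes changed at T65 day 12 depended on replicate 2 of its 2 libraries. Changes wholly absent from replicate 1 are argued against, since 80.4% of 1812 genes lay the same way in replicate 1 against the 2 day 4 libraries of the same share (those of the 1881 called without replicate 1 that were also tested with all libraries). The median change was 0.195 in replicate 1 and 0.64 in replicate 2 for genes called higher, and -0.184 and -0.696 for genes called lower, where choosing the genes on replicate 2 by itself widens the gap. Depth is argued against, since with every library thinned to 8.61 M the count was 1424 without replicate 1 and 61 without replicate 2. The split by multiply aligned reads as the source of a difference between replicates 1 and 2 is argued against, since both lie in the higher share (10.2 and 9.59%), and a state of replicate 2 further along in the response stays open, untested.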

How the results depend on the processing

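The alternatives built on multiply aligned reads (the split as a term, and the 16 or the 7 libraries alone) were chosen after the data were seen. Of 379 results for named genes, the direction and side of the threshold were the same in 372 with RLE size factors, 342 with no filter, 357 with DESeq2, 363 with a replicate block, 316 with only the groups compared, 347 with the split as a term and 200 in the 16 libraries. There 177 were weaker, with fewer libraries, and 2 reversed without passing: OsRR9 at T65 day 4 (0.36 against -0.34) and PIN1d at T65 day 12 (0.1 against -0.42). Leaving out 1 library gave 3110 same, 609 weaker and 6 stronger. No count moved by over 1.5 times with RLE size factors. For other settings below, the cause was not tested beyond the fewer libraries or groups named.

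With only the groups compared, the counts were 1106 at NB day 4 (below the 4214 at NB day 12), 132 at T65 day 4, and 61 and 1 for the interactions at day 4 and day 8. With no filter they were 1703 at NB day 8, 513, 844 and 2254 at T65 day 4, 8 and 12, 995, 183 and 2432 for the interactions, and 612 for the overlap of day 12. DESeq2 gave 904 at NB day 8, 97 and 462 at T65 day 4 and 8, and 900 and 21 for the interactions at day 4 and day 8. The replicate numbers were not shown to pair the libraries, since 9 of 33 same-numbered pairs had a correlation over 0.1 (-0.4 to 0.496) and no other pairs were compared. With the replicate block the counts were 52 at T65 day 4, 1 for the interaction at day 8 and 15 list calls in place of 26. The split as a term gave 794 for the interaction at day 12. An estimated correlation left 2 of 26 list calls.

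In the 16 libraries of the higher share the counts were 3071, 97 and 1187 for NB, 1, 2 and 13 for T65, 13, 1 and 13 for the interactions, 3651 between cultivars and 9 for the overlap. In the 7 of the lower share they were 6 and 150 at T65 day 4 and 8, and the other comparisons lacked a group. Without 1 library the counts ranged from 2328 to 6982, 167 to 545 and 1345 to 2680 for NB day 4, 8 and 12, and from 14 to 21, 69 to 153 and 97 to 1881 for T65. They ranged from 53 to 1088, 1 to 3 and 237 to 2132 for the interactions, 5642 to 7798 between cultivars and 52 to 261 for the overlap. A group left with 1 library is assumed to vary like the others. Thinning every library to 8.61 M counts left 3915 genes at NB day 4 and 1057 at T65 day 12.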

Other observations

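The tests on the share of multiply aligned reads in this part were chosen only after the result was seen. Reads aligned to several places split the libraries into 7 and 16, and the groups held them unequally, with all libraries of NB day 0, NB day 4 and T65 day 12 in the higher set. Against the other 16 libraries, 452 genes were higher and 507 lower in the 7 libraries. There were 7 genes with 0 counts in all of the 7 and at least 10 counts in each of the 16, LOC_Os01g51740 among them, and 0 genes the other way round. The labels give no sequencing or library batch.

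The third pattern is that genes at least 2-fold different between the cultivars were more often lower in T65 (821) than higher (273). The short-day response as the cause is argued against by day 0, where 73% of such genes were lower (526 against 195), while the share was 78.6%, 71% and 59.1% on days 4, 8 and 12. The 73% fits reads of T65 mapping less well to gene models that may derive from NB, whose build is not given in the sources used here. Neighbouring genes fit too: 143 of the lower genes were followed by another, against at most 51 (median 29) in 10000 random orders (permutation p = 1e-04, the smallest they can give), and 32 of the higher, against at most 11 (median 3), while 19 genes were off in T65 and on in NB and 11 the other way. Genes absent from T65, reads that do not map and a difference in transcription stay open.

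Splits of the 6 libraries of a day and day 0 into groups of 3 number 10, too few for a share under 0.05. The real count was the highest, as 1 of 10 splits, in each: NB day 4 4631 (highest other 1), NB day 8 505 (1), NB day 12 3023 (0), T65 day 4 34 (0) and T65 day 8 243 (0). For T65 against NB over the 4 days, 40 splits were used, the real one and others drawn at random. Only the real one gave as many as 6807 genes, the highest other being 921. A share of 1 in 40 is the smallest these splits can give. It argues against chance at 0.05 but does not exclude it, and the labels do not say that the libraries came from separate plants.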
